A study of Mus musculus with 24 samples.

How the data were processed

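RNA-seq was made from mouse oocytes of 2 genotypes, wild type (WT, Snf2h flox/flox) and conditional knockout (KO, ZP3-Cre with Snf2h flox/flox). Cre is given for the KO only, so each KO-WT difference may hold an effect of the Cre transgene beside that of Snf2h loss. These cannot be separated here. Snf2h is the protein encoded by Smarca5. There were 4 stages: GO1 (growing, 40 to 45 µm), GO2 (growing, 50 to 55 µm), nFGO (fully grown, above 70 µm, collected without hormone) and FGO (fully grown, collected after hormone). Each of the 8 groups had 2 libraries of 20 oocytes, 16 libraries in all. The labels do not say that replicates came from separate animals, so the p-values here measure only the spread between these samples. The 4 nFGO libraries carry a polyA RNA label and the other 12 a total RNA label. The labels do not show whether this is a difference in preparation or only in labelling. The nFGO libraries also entered the series later, so any difference between nFGO and another stage within 1 genotype may hold a batch difference. The 8 ATAC-seq samples of the series were not analysed here.

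The deposited table holds, per the file headers, 1 RPKM value per gene and library. Per the submitters' processing notes the reads were handled with Trim Galore 0.4.5, HISAT2 2.1.0, Cufflinks 2.2.1 with Cuffnorm, DESeq 1.34.1 and deepTools 3.0.2, on mm10. For each stage the authors also give DESeq output, with the mean count of each group, a log2 fold change of KO over WT, a p-value and the group called up or down. The deposited log2 fold change equals the log2 ratio of the deposited mean counts. The deposited p-value is not stated to be adjusted or unadjusted, and it was not used in any test here.

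The table had 18060 lines for 16975 gene IDs. A set of 35 IDs was written 32 times each with 2 different sets of nFGO values, and these were left out, among them Ddit3, Aldoa, Gcat, Atp5o and Sept2. Of the IDs, 16971 were matched to a symbol in the name table, and 20 symbols stored as spreadsheet dates were restored through their IDs. This left 16940 genes, 174 of them at 0 in every library. RPKM totals ran from 832384 to 1011538 per library, 12613 to 12919 genes reached 1 RPKM, and the 10 highest genes held 6.74 to 8.16 percent of a total. Replicates correlated at r = 0.980 to 0.990 across genes, which are not independent replicates.

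Whole reads could not be recovered from the RPKM values: only 16.2 to 26.5 percent of the ratios of low values between libraries lay at ratios of small whole numbers. The depth of each library is therefore not known here. The commonest ratio between low values gave a relative depth of 0.597 to 1.09 against WT GO1 replicate 1, an uncertain estimate on which no result rests.

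Values were taken as log2(RPKM + 1). Genes with at least 1 RPKM in at least 2 libraries were tested, 14557 in all. With a pseudocount of 1, a fold change computed from these values understates the change of genes near or below 1 RPKM. limma 3.58.1 in R 4.3.3 was used with 1 mean per group over all 16 libraries (8 residual degrees of freedom), no replicate block, and moderated t tests with a variance trend (4.01 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were KO against WT at each stage, WT growth between stages, FGO against nFGO in each genotype, and 3 interactions, each the KO effect at 1 stage less that at another. Groups are given as mean ± SD of RPKM with n = 2 libraries, and changes as log2 fold change, which stands alone in brackets before an adjusted p.

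The samples, comparisons, tests and first set of alternatives were fixed before the data were examined. The procedure was tested on simulated data, with 50 genes per fold change, all at 5 RPKM or more before the change, added to the measured spread. It recovered 28 to 36 percent of 1.5-fold, 64 to 72 percent of 2-fold and 98 to 100 percent of 4-fold changes, and 3.29 to 5.23 percent of its calls were false. The simulation drew independent normal noise for each gene, with the spread that limma fitted. It held no correlation between genes and no outlying library, so its false share may not carry over to these data. Changes in genes under 5 RPKM were not simulated, so the recovery may not carry over to them.

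For each KO-WT comparison the 10 largest rises and 10 largest falls with at least 5 RPKM in the higher group were listed, and 5 each for the other comparisons. From every gene list up to 4 called members with the largest change were taken. The genes named below were chosen among these. Only genes that kept their call with each library of the compared groups left out are given as examples, unless the text says otherwise. Below, every or each library left out means these libraries for single genes, gene counts and camera calls of lists, unless the text counts more. Of the genes so listed, Smarca5 not counted, 20 of 69 kept their call at GO1, 8 of 68 at GO2, 39 of 101 at nFGO and 54 of 106 at FGO.

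A further 31 gene lists were written from known function before the test, and 28 with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with the other genes, while fry tests its members against no change. The fry p-values given are for a shift of the members in 1 direction. They covered maturation-promoting factor (MPF) activation and meiotic resumption, prophase arrest and cAMP-PKA signalling, the anaphase-promoting complex and spindle checkpoint, the spindle and cytoskeleton, meiotic cohesion and recombination, zona pellucida and oocyte-secreted factors, oocyte transcription factors, maternal-effect genes, translational control, ISWI complexes, other chromatin remodellers, DNA and histone methylation, piRNA and transposon control, 2-cell stage genes, imprinted genes, p53 and DNA damage, the unfolded protein and integrated stress response, heat shock proteins, growth kinase signalling, cholesterol synthesis, glycolysis, calcium and egg activation, and markers of granulosa, cumulus, theca and blood or endothelial cells. Replication-dependent histones, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded transcripts and the proteasome were taken by symbol pattern. Camera p-values were adjusted over the lists within a comparison, and list tests outside the 4 KO-WT comparisons, the adjustment of fry p-values over the lists and fry under the alternatives were added after the data were seen.

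Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 RPKM, quantile normalization, equal library medians, no variance trend, a replicate block, leaving out each library in turn, and for KO-WT comparisons a fit of only the 4 libraries of the stage. Chosen after the data were seen were 2 more: keeping only calls whose direction the authors' fold shares, and leaving out small RNA, immunoglobulin, Gm and pseudogene symbols. When a library is left out of a group of 2, the lone sample left is assumed to vary like the other groups.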

Results

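Smarca5 (ENSMUSG00000031715.14, chromosome 8, 80698507 to 80739497, minus strand, mm10), the deleted gene, fell in KO oocytes at every stage (mean ± SD, n = 2 libraries per group). At GO1 it fell from 41.5 ± 2.14 to 1.83 ± 0.316 RPKM (log2 fold change -3.91, adjusted p = 0.000499). At GO2 it fell from 37.7 ± 0.81 to 1.51 ± 0.744 RPKM (log2 fold change -3.98, adjusted p = 0.000669). At nFGO it fell from 46.5 ± 2.09 to 1.25 ± 0.101 RPKM (log2 fold change -4.40, adjusted p = 7.81e-05). At FGO it fell from 31.3 ± 24.6 to 0.824 ± 0.173 RPKM (log2 fold change -3.90, adjusted p = 9.41e-05). Tests are limma with Benjamini-Hochberg adjustment. The 2 WT FGO libraries stood apart for this gene, at 48.7 RPKM in replicate 1 and 13.9 RPKM in replicate 2. The FGO log2 fold change was -3.04 without WT FGO replicate 1 and -4.77 without WT FGO replicate 2, and both passed the test.

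Mt1 (ENSMUSG00000031765.8, chromosome 8, 94179082 to 94180327, plus strand), which encodes the metal-binding protein metallothionein 1, had the largest rise at all 4 stages. It rose at GO1 from 7.11 ± 0.0204 to 1900 ± 246 RPKM (log2 fold change 7.87, adjusted p = 1.35e-07). It rose at GO2 from 5.12 ± 0.278 to 1405 ± 134 RPKM (log2 fold change 7.84, adjusted p = 1.4e-07). It rose at nFGO from 7.19 ± 0.405 to 2225 ± 896 RPKM (log2 fold change 8.03, adjusted p = 1.06e-07). It rose at FGO from 5.51 ± 3.1 to 2060 ± 608 RPKM (log2 fold change 8.36, adjusted p = 6.57e-08). Every one of the 8 KO libraries lay between 1310 and 2859 RPKM and every WT library between 3.32 and 7.7 RPKM (n = 2 per group). The lowest KO library held 170 times the highest WT library. A test below of Mt1 sequence carried by the Cre transgene did not decide, so a rise of the endogenous gene is not shown.

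**Figure D1:**
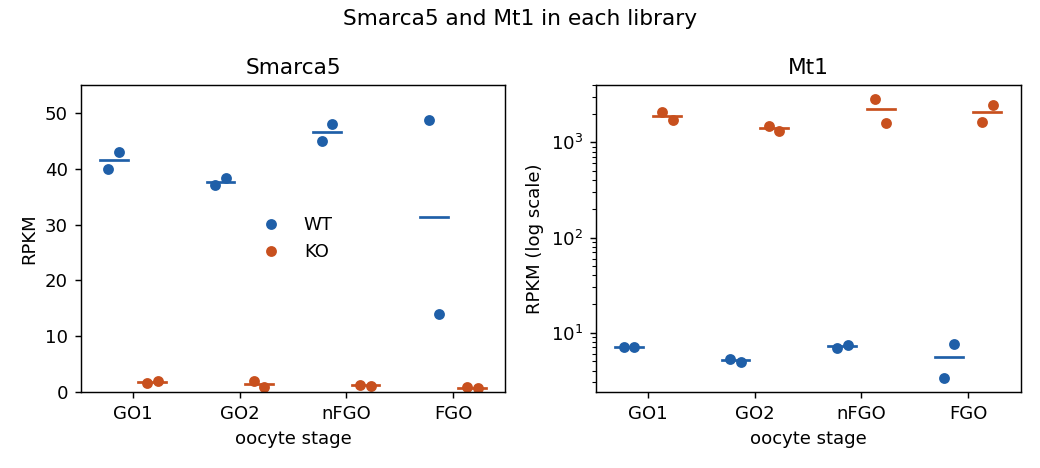
RPKM of Smarca5 and Mt1 in each library (points, n = 2 per group) with the group mean (bar), Mt1 on a log scale. Smarca5 was 13.9 RPKM in WT FGO replicate 2 and 48.7 RPKM in replicate 1, while Mt1 was at 1310 RPKM or more in every KO library.

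In the smallest oocytes, GO1, the ephrin ligand Efna1 rose from 17.1 ± 4.97 to 59.5 ± 8.75 RPKM (log2 fold change 1.76, adjusted p = 0.00201). The linker histone gene Hist1h1c rose from 5.75 ± 1.99 to 20.2 ± 3.85 RPKM (log2 fold change 1.67, adjusted p = 0.00157) and the uracil-DNA glycosylase gene Ung from 8.36 ± 1.39 to 27.2 ± 3.09 RPKM (log2 fold change 1.60, adjusted p = 0.000395). So did the transcription factor gene Tfec, from 0.608 ± 0.243 to 5.84 ± 2.02 RPKM (log2 fold change 2.06, adjusted p = 0.00444). Among genes that fell, the ETS factor gene Ehf went from 123 ± 10.8 to 27.3 ± 7.49 RPKM (log2 fold change -2.16, adjusted p = 0.000205) and Lrrc17 from 96.1 ± 19 to 18.6 ± 7.19 RPKM (log2 fold change -2.34, adjusted p = 0.000289). Falls were also seen for Akr1b8 from 15.5 ± 4.25 to 2.23 ± 0.3 (-2.33, adjusted p = 0.000603) and Timd4 from 12.7 ± 1.77 to 1.92 ± 0.897 (-2.26, adjusted p = 0.000545) RPKM. Gbp7 from 7.37 ± 2.14 to 0.483 ± 0.216 (-2.48, adjusted p = 0.000717) and Arl8a from 23.6 ± 0.143 to 4.57 ± 1.29 (-2.16, adjusted p = 0.00433) RPKM fell, as did Rgs10 (-1.85, adjusted p = 0.00296). The oogenesin genes Oog2 from 239 ± 27.6 to 78.8 ± 30.6 (-1.64, adjusted p = 0.00136) and Oog3 from 421 ± 82.9 to 139 ± 51.6 (-1.63, adjusted p = 0.00103) RPKM fell too. So did Ago2 (-1.04, adjusted p = 0.00159), Pecam1 (-1.20, adjusted p = 0.00368), Mest (-0.99, adjusted p = 0.00531), Zfp750 (-0.94, adjusted p = 0.00175) and Atrx (-0.78, adjusted p = 0.00174), given as log2 fold change and adjusted p. All values are mean ± SD of n = 2 libraries.

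With limma and Benjamini-Hochberg adjustment, 965 genes passed the test at GO1, 314 higher and 651 lower in KO, 275 of them changed at least 2-fold. With only the 4 libraries of the stage the count was 16. With library medians made equal the split was 438 higher and 568 lower. The count was 231 without WT GO1 replicate 1, 241 without WT GO1 replicate 2, 243 without KO GO1 replicate 1 and 2741 without KO GO1 replicate 2.

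Cytosolic ribosomal protein genes were higher at GO1, by a median of 0.29 on the log2 scale: 22 of 85 rose and 0 fell over all genes (43 and 1 adjusted over the list alone), camera adjusted p = 3.05e-20, and adjusted p = 0.193 with an estimated correlation. Nuclear oxidative phosphorylation genes had a median of 0.20: 15 of 86 rose and 0 fell over all genes (29 and 0 adjusted over the list alone), camera adjusted p = 1.09e-10, and adjusted p = 0.193 with an estimated correlation, with Uqcr10 (0.50, adjusted p = 0.00345) among those that rose. Both calls held with every library left out. Replication-dependent histones were higher as a group, with Hist1h1c as the 1 called gene: 1 of 27 rose and 0 fell over all genes (1 and 0 adjusted over the list alone), camera adjusted p = 0.0339, and adjusted p = 0.241 with an estimated correlation. That call was lost without WT GO1 replicate 2 (0.143) and without KO GO1 replicate 2 (0.0762), and with the 5 RPKM filter (0.106).

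Zona pellucida and oocyte-secreted factor genes, with Oog2 and Oog3 above, were lower at GO1: 1 of 22 rose and 7 fell over all genes (1 and 7 adjusted over the list alone), camera adjusted p = 0.0428, and adjusted p = 0.407 with an estimated correlation. The call was lost without WT GO1 replicate 1 (0.0919) and without KO GO1 replicate 1 (0.0918). It was also lost with the 5 RPKM filter (0.0953), equal library medians (0.0535) and no variance trend (0.0576). Heat shock genes were lower: 0 of 12 rose and 1 fell over all genes (0 and 2 adjusted over the list alone), camera adjusted p = 0.0428, and adjusted p = 0.193 with an estimated correlation, with the call lost without WT GO1 replicate 1 (0.103) and without KO GO1 replicate 2 (0.111). The 5 RPKM filter (0.106), equal medians (0.066) and no variance trend (0.0808) lost it too. Cholesterol synthesis genes were lower: 0 of 19 rose and 1 fell over all genes (0 and 1 adjusted over the list alone), camera adjusted p = 0.0428, and adjusted p = 0.193 with an estimated correlation. This call was lost without WT GO1 replicate 1 (0.0672), WT GO1 replicate 2 (0.111), KO GO1 replicate 1 (0.0918) or KO GO1 replicate 2 (0.0762), with the 5 RPKM filter (0.113) and with no variance trend (0.0559). DNA and histone methylation genes had a median log2 fold change of 0.225, though 0 of 32 rose and 1 fell over all genes (0 and 1 adjusted over the list alone). Camera called the list higher (adjusted p = 0.0428, and 0.407 with an estimated correlation), while directional fry did not pass (adjusted p = 0.119). The camera call was lost without WT GO1 replicate 1, WT GO1 replicate 2 or KO GO1 replicate 1, and with no variance trend (0.0559). Of MPF and meiotic resumption genes at GO1, 1 of 22 rose and 1 fell over all genes (3 and 6 adjusted over the list alone), camera adjusted p = 0.435.

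At GO2, Tfec rose from 0.45 ± 0.198 to 8.42 ± 1.75 RPKM (log2 fold change 2.69, adjusted p = 0.00153), as it did at GO1. The ubiquitin ligase gene March11 rose from 0.257 ± 0.0764 to 5.59 ± 2.42 RPKM (log2 fold change 2.34, adjusted p = 0.000977) and the lipase family gene Pnpla5 from 0.362 ± 0.194 to 5.2 ± 2.01 RPKM (log2 fold change 2.15, adjusted p = 0.00171). So did the pregnancy-specific glycoprotein gene Psg16, from 9.92 ± 0.163 to 43.1 ± 0.835 RPKM (log2 fold change 2.01, adjusted p = 0.000868). The small GTPase gene Arl5c fell from 67.7 ± 2.04 to 3.47 ± 1.2 RPKM (log2 fold change -3.97, adjusted p = 0.00144). Ube2s, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 496 ± 62.2 to 214 ± 71 RPKM (log2 fold change -1.24, adjusted p = 0.00386). The cytochrome c oxidase gene Cox6b2 fell from 596 ± 22.9 to 327 ± 62.3 RPKM (log2 fold change -0.88, adjusted p = 0.00316). All are mean ± SD of n = 2 libraries. Smarca5 not counted, only 8 of 68 listed genes at GO2 kept their call with each library left out. Arl8a (-2.19, adjusted p = 0.00471), Hspb1 (-2.06, adjusted p = 0.0064) and Psmb2 (-0.51, adjusted p = 0.00534) also fell, and lost the call without KO GO2 replicate 2.

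In limma at GO2, 1112 genes passed the test, 431 higher and 681 lower, 317 of them changed at least 2-fold. Quantile normalization gave 551 higher and 527 lower, and the 4 libraries of the stage alone 291 genes. The count was 362 without WT GO2 replicate 1, 196 without WT GO2 replicate 2, 452 without KO GO2 replicate 1 and 61 without KO GO2 replicate 2.

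Ribosomal protein genes were lower at GO2, with a median log2 fold change of -0.29: 0 of 85 rose and 28 fell over all genes (0 and 55 adjusted over the list alone), camera adjusted p = 1.26e-17, and adjusted p = 0.265 with an estimated correlation. Oxidative phosphorylation genes, with Cox6b2 among them, had a median of -0.28: 1 of 86 rose and 27 fell over all genes (2 and 51 adjusted over the list alone), camera adjusted p = 2.77e-14, and adjusted p = 0.265 with an estimated correlation. Both calls held with every library left out. The KO GO2 libraries had the lowest RPKM totals, 845600 and 832384. With quantile normalization the ribosomal median was -0.16 (camera adjusted p = 7.37e-08) and the oxidative phosphorylation median -0.11 (adjusted p = 0.000179). Of heat shock genes, 0 of 12 rose and 3 fell over all genes (0 and 3 adjusted over the list alone), camera adjusted p = 0.0691. Of zona and oocyte-secreted factor genes, 0 of 22 rose and 5 fell over all genes (0 and 5 adjusted over the list alone), camera adjusted p = 0.0691. Of maternal-effect genes, 0 of 33 rose and 2 fell over all genes (0 and 2 adjusted over the list alone), camera adjusted p = 0.0691. Of glycolysis genes, 0 of 14 rose and 0 fell over all genes (0 and 0 adjusted over the list alone), camera adjusted p = 0.0691. With KO GO2 replicate 2 left out, the adjusted p was 0.0375 for each of these 4 lists and for 2-cell stage genes. Of 2-cell stage genes, 2 of 11 rose and 0 fell over all genes (4 and 1 adjusted over the list alone), camera adjusted p = 0.134.

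The KO effect on ribosomal protein genes differed between GO2 and GO1 by a median of -0.57 on the log2 scale: 0 of 85 genes passed with a more positive and 42 with a more negative effect over all genes (0 and 68 adjusted over the list alone), camera adjusted p = 1.83e-35, and adjusted p = 0.0492 with an estimated correlation. Mean log2 levels of these genes were 7.40 and 7.34 in the WT GO1 libraries and 7.67 and 7.61 in KO. They were 7.56 and 7.51 in WT GO2 and 7.29 and 7.25 in KO. Oxidative phosphorylation genes differed by a median of -0.52: 1 of 86 genes passed with a more positive and 36 with a more negative effect over all genes (1 and 55 adjusted over the list alone), camera adjusted p = 3.78e-24, and adjusted p = 0.0492 with an estimated correlation. With each library left out in turn and the preset correlation, the ribosomal adjusted p ran from 6.45e-38 to 3.89e-25 (16 fits of limma). Both calls with the estimated correlation stayed only without WT GO1 replicate 1 (0.0451) or either KO FGO replicate (0.047), and were lost without any 1 of the other 13 libraries, up to 0.165 without KO GO1 replicate 2. They were also lost with quantile normalization (0.167), the 5 RPKM filter (0.0652) and a pseudocount of 5 (0.0503). With quantile normalization the preset-correlation adjusted p was 2.63e-26 for ribosomal and 1.32e-13 for oxidative phosphorylation genes. Their KO medians at GO1 and GO2 were then 0.31 and -0.16 (ribosomal) and 0.20 and -0.11 (oxidative phosphorylation). Of 2-cell stage genes, 2 of 11 genes passed with a more positive and 0 with a more negative effect over all genes (2 and 0 adjusted over the list alone), camera adjusted p = 0.0284, and adjusted p = 0.603 with an estimated correlation, lost without WT GO1 replicate 1 (0.153), KO GO1 replicate 1 (0.083) or KO GO2 replicate 1 (0.0703), with the 5 RPKM filter (0.218) and with a pseudocount of 0.1 (0.0724). Of glycolysis genes, 0 of 14 genes passed with a more positive and 0 with a more negative effect over all genes (2 and 0 adjusted over the list alone), camera adjusted p = 0.0284, and adjusted p = 0.177 with an estimated correlation, lost without WT GO1 replicate 1 (0.0659), KO GO1 replicate 1 (0.083), WT GO2 replicate 1 (0.0623) or KO GO2 replicate 1 (0.0703), with the 5 RPKM filter (0.33) and with a pseudocount of 0.1 (0.0566). These list tests of interactions were added after the data were seen.

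Ube2s had an interaction of -1.90 (adjusted p = 0.0108) and was the 1 gene of 45 listed that kept its call with every library left out. Its KO effect was -1.24 at GO2 and 0.66 at GO1 (adjusted p = 0.0494), where the call was lost without any 1 of the 4 GO1 libraries. Dnmt3l (1.71, adjusted p = 0.0092), which encodes a cofactor of de novo DNA methylation, had a more positive effect at GO2 and lost its call without KO GO2 replicate 2. In all 582 genes passed, 268 with a more positive effect at GO2 and 314 with a more negative one. Quantile normalization gave 279 and 186, and equal library medians 231 and 413. With no variance trend 101 genes passed, and a replicate block left far fewer, as given in the part on processing. The count was 97 without WT GO1 replicate 1, 25 without WT GO1 replicate 2, 126 without KO GO1 replicate 1 and 2402 without KO GO1 replicate 2. It was 140 without WT GO2 replicate 1, 25 without WT GO2 replicate 2, 184 without KO GO2 replicate 1 and 4 without KO GO2 replicate 2.

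**Figure D2:**
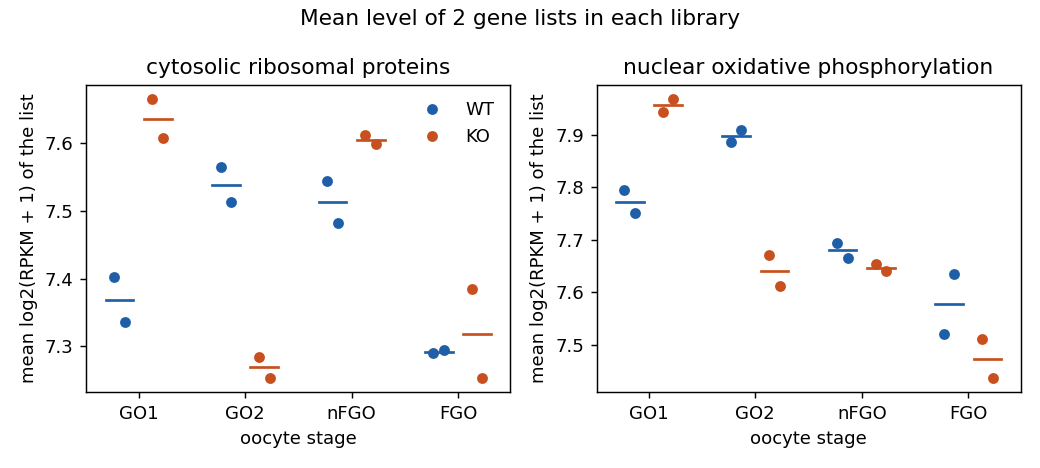
Mean log2(RPKM + 1) of cytosolic ribosomal protein and nuclear oxidative phosphorylation genes in each library (points, n = 2 per group) with the group mean (bar). Ribosomal protein genes were at 7.67 and 7.61 in KO GO1 and at 7.29 and 7.25 in KO GO2.

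In fully grown oocytes collected without hormone, the linker histone gene Hist1h1e rose from 0.506 ± 0.247 to 9.28 ± 1.35 RPKM (log2 fold change 2.77, adjusted p = 3.92e-05) and Hist1h1c (1.73, adjusted p = 0.000451) rose too. The beta-defensin gene Defb41 rose from 67 ± 13.2 to 379 ± 13 RPKM (log2 fold change 2.50, adjusted p = 0.000307). Rises also held for Igsf21 from 0.379 ± 0.264 to 8.09 ± 2.07 (2.71, adjusted p = 7.81e-05) and Mterf2 from 1.65 ± 0.634 to 13.6 ± 0.406 (2.48, adjusted p = 0.000371) RPKM. Klhdc8b (2.18, adjusted p = 0.000374), March11 (2.06, adjusted p = 0.000342) and Tfec (2.02, adjusted p = 0.0018) rose as well. The aldo-keto reductase gene Akr1b8 (ENSMUSG00000029762.6, chromosome 6, 34354119 to 34368463, plus strand) fell from 65.8 ± 6.27 to 1.69 ± 0.296 RPKM (log2 fold change -4.63, adjusted p = 2.54e-06). Got1, which encodes cytosolic aspartate aminotransferase, fell from 64 ± 2.98 to 4.25 ± 2.47 RPKM (log2 fold change -3.71, adjusted p = 4.65e-05). The adhesion receptor gene Adgrv1 fell from 11.2 ± 0.0274 to 0.523 ± 0.0129 RPKM (log2 fold change -3.00, adjusted p = 4.13e-06) and the calcium-binding protein gene Calb1 from 24.4 ± 3.01 to 2.4 ± 0.342 RPKM (log2 fold change -2.90, adjusted p = 0.000189). Falls also held for Igf1os from 82.1 ± 6.7 to 5.82 ± 0.73 (-3.61, adjusted p = 7.81e-05) and Pcp4 from 13 ± 2.1 to 1.1 ± 1.01 (-2.81, adjusted p = 0.000295) RPKM. Arl5c (-2.92, adjusted p = 0.00168) and Prelid2 (-2.67, adjusted p = 0.00512) fell as well. All are mean ± SD of n = 2 libraries.

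Dppa3, a maternal-effect gene, fell at nFGO from 6112 ± 186 to 3828 ± 333 RPKM (log2 fold change -0.68, adjusted p = 0.00279). The chromatin remodeller gene Atrx fell from 310 ± 8.73 to 92.1 ± 10.7 RPKM (log2 fold change -1.74, adjusted p = 4.13e-06). The spindle genes Ckap5 (-0.92, adjusted p = 0.00304) and Ndc80 (-0.79, adjusted p = 0.000307) and the spindle checkpoint gene Bub1b (-0.85, adjusted p = 0.00288) fell, while Mad2l1bp (0.67, adjusted p = 0.00423) rose. The meiotic prophase gene Meioc (-1.62, adjusted p = 7.79e-05) fell. So did Ago2 (-0.82, adjusted p = 0.00244), Dnmt3a (-0.55, adjusted p = 0.00376), Nsd1 (-0.83, adjusted p = 0.00376), Asz1 (-0.87, adjusted p = 0.000961), Impact (-1.35, adjusted p = 0.00148) and Rps6ka3 (-0.69, adjusted p = 0.00164). Among heat shock genes Hsp90ab1 (-0.60, adjusted p = 0.00142) and Hspe1 (-0.59, adjusted p = 0.00449) fell. Rpl9 (0.99, adjusted p = 0.000527) and Psmb3 (0.64, adjusted p = 0.00423) rose and Rpl21 (-0.45, adjusted p = 0.00658) fell.

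By limma, 2354 genes passed the test at nFGO, 985 higher and 1369 lower, 650 of them changed at least 2-fold. Quantile normalization gave 1108 higher and 1173 lower, and the 4 libraries of the stage alone 1174 genes. The count was 1374 without WT nFGO replicate 1, 974 without WT nFGO replicate 2, 960 without KO nFGO replicate 1 and 1315 without KO nFGO replicate 2.

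Heat shock genes were lower at nFGO, with a median log2 fold change of -0.35: 0 of 12 rose and 6 fell over all genes (0 and 7 adjusted over the list alone), camera adjusted p = 0.00328, and adjusted p = 0.118 with an estimated correlation. With quantile normalization that median was -0.22 (adjusted p = 0.00667). Histone genes were higher, with a median of 0.41: 5 of 27 rose and 0 fell over all genes (5 and 0 adjusted over the list alone), camera adjusted p = 0.00328, and adjusted p = 0.301 with an estimated correlation. Spindle and cytoskeleton genes were lower: 1 of 36 rose and 7 fell over all genes (1 and 7 adjusted over the list alone), camera adjusted p = 0.0298, and adjusted p = 0.573 with an estimated correlation. The spindle call was lost without WT nFGO replicate 2 (0.187), without KO nFGO replicate 1 (0.0601), with quantile normalization (0.0878), with the 5 RPKM filter (0.0592) and with no variance trend (0.0589). Of MPF genes, 0 of 22 rose and 5 fell over all genes (1 and 8 adjusted over the list alone), camera adjusted p = 0.0622, and the adjusted p was 0.0496 without WT nFGO replicate 1 and 0.0401 without KO nFGO replicate 2, and 0.0491 with no filter. Of ribosomal protein genes, 9 of 85 rose and 3 fell over all genes (7 and 3 adjusted over the list alone), camera adjusted p = 0.0622, with 0.00739 without WT nFGO replicate 1, 0.00667 with quantile normalization and 0.0229 with equal library medians.

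Granulosa cell markers were examined as a possible source of RNA from other cells, and 9 of 10 were tested in these libraries. At nFGO the median was 0.24: 2 of 9 rose and 1 fell over all genes (3 and 2 adjusted over the list alone), camera adjusted p = 0.601. Inha rose from 1.7 ± 1.6 to 8.8 ± 5.61 RPKM (log2 fold change 1.87, adjusted p = 0.0112), but lost its call without WT nFGO replicate 1 and without KO nFGO replicate 2. Cdh2 (-0.93, adjusted p = 0.00465) fell. At GO2 the median was 0.41: 1 of 9 rose and 0 fell over all genes (1 and 0 adjusted over the list alone), camera adjusted p = 0.265, and 0.0266 with the 5 RPKM filter.

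After hormone, the secreted growth factor gene Fgf21 (ENSMUSG00000030827.5, chromosome 7, 45613886 to 45615490, minus strand) rose in KO oocytes from 0.0665 ± 0.0941 to 58.1 ± 17.8 RPKM (log2 fold change 5.76, adjusted p = 0.00128). The kelch-domain gene Klhdc8b rose from 0.437 ± 0.262 to 16.2 ± 1.97 RPKM (log2 fold change 3.59, adjusted p = 1.7e-05) and Efna1 from 34.8 ± 10.5 to 200 ± 7.27 RPKM (log2 fold change 2.52, adjusted p = 6.06e-05). So did the apoptosis inhibitor gene Birc7, from 0.689 ± 0.108 to 8.56 ± 1.69 RPKM (log2 fold change 2.49, adjusted p = 2.09e-05). Rises also held for Hist1h1e from 0.385 ± 0.056 to 6.73 ± 1.99 (2.46, adjusted p = 3.89e-05) and Igsf21 from 0.27 ± 0.0255 to 6.44 ± 0.216 (2.55, adjusted p = 6.48e-05) RPKM, and for Hist1h1c (1.80, adjusted p = 0.000306), Hmgn3 (2.40, adjusted p = 0.00128) and Krt79 (2.36, adjusted p = 0.0031). Akr1b8 fell from 59.1 ± 13.4 to 2.45 ± 0.162 RPKM (log2 fold change -4.10, adjusted p = 4.51e-06) and Adgrv1 from 10.2 ± 1.96 to 0.201 ± 0.0343 RPKM (log2 fold change -3.21, adjusted p = 2.92e-06). The membrane glycoprotein gene Cd200 fell from 21.7 ± 2.68 to 0.817 ± 0.253 RPKM (log2 fold change -3.65, adjusted p = 5.58e-05). Falls also held for Igf1os from 59.2 ± 2.19 to 3.71 ± 2.32 (-3.77, adjusted p = 3.89e-05) and Tnip3 from 21.2 ± 0.622 to 1.46 ± 0.0336 (-3.18, adjusted p = 2.88e-05) RPKM, and for Calb1 (-3.21, adjusted p = 7.12e-05) and Tuba3b (-3.01, adjusted p = 0.00219). All are mean ± SD of n = 2 libraries.

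Single genes of meiosis and cell division fell at FGO. The B-type cyclin gene Ccnb2 fell from 220 ± 10.1 to 130 ± 8.5 RPKM (log2 fold change -0.75, adjusted p = 0.00108), and Ccnb3 (-0.94, adjusted p = 0.00441) fell. The augmin subunit gene Haus1, whose complex nucleates microtubules within the spindle, fell from 142 ± 5.36 to 38.4 ± 0.0926 RPKM (log2 fold change -1.85, adjusted p = 0.00734). The meiotic recombination gene Mei4 fell from 80.4 ± 0.365 to 15 ± 8.21 RPKM (log2 fold change -2.45, adjusted p = 0.00016). The kinetochore gene Ndc80 (-0.70, adjusted p = 0.000526), the checkpoint kinase gene Ttk (-0.45, adjusted p = 0.00447) and Meioc (-0.99, adjusted p = 0.000893) fell, and Mad2l1bp (0.66, adjusted p = 0.00378) rose. The deadenylase gene Cnot7 (-0.60, adjusted p = 0.00798) and the Argonaute genes Ago2 (-1.05, adjusted p = 0.000449) and Ago3 (-0.76, adjusted p = 0.00105) fell. Of genes of the ISWI complexes, Chrac1 (1.38, adjusted p = 0.00134) rose and Baz1a (-1.15, adjusted p = 0.0002), which encodes a partner of Snf2h, fell. Atrx (-1.04, adjusted p = 8.47e-05), Mcts2 (-1.88, adjusted p = 0.00048) and Plk2 (-1.10, adjusted p = 0.00054) fell, and Btg2 (0.99, adjusted p = 0.00114) rose.

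Lists with a role in meiotic resumption did not pass with camera at FGO. Of MPF genes, Ccnb2 and Ccnb3 included, 1 of 22 rose and 6 fell over all genes (1 and 8 adjusted over the list alone), camera adjusted p = 0.34. Of prophase arrest and cAMP genes, 1 of 19 rose and 2 fell over all genes (1 and 2 adjusted over the list alone), camera adjusted p = 0.92. Of anaphase-promoting complex and spindle checkpoint genes, 2 of 28 rose and 4 fell over all genes (2 and 5 adjusted over the list alone), camera adjusted p = 0.634. Of spindle genes, 0 of 36 rose and 5 fell over all genes (0 and 5 adjusted over the list alone), camera adjusted p = 0.339. Of meiotic cohesion and recombination genes, Mei4 and Meioc included, 2 of 27 rose and 5 fell over all genes (2 and 5 adjusted over the list alone), camera adjusted p = 0.731. Of maternal-effect genes, 2 of 33 rose and 9 fell over all genes (3 and 9 adjusted over the list alone), camera adjusted p = 0.287. Maternal-effect genes had 0.0178 without WT FGO replicate 1.

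Fry of limma, directional and adjusted over the lists, passed 11 of 28 lists at GO1, 6 at GO2, 12 at nFGO and 7 at FGO. With quantile normalization these were 11, 4, 8 and 3. Fry tests against no change, so the scaling can matter, but the cause of these changes was not tested. At FGO, MPF (adjusted p = 0.0216), maternal-effect (0.0109) and anaphase-promoting complex/spindle checkpoint genes (0.043) were lower. All 3 calls were lost with quantile normalization (0.0891, 0.314 and 0.793). The MPF call was also lost without any 1 of the 4 FGO libraries, up to 0.176, and the maternal-effect call without KO FGO replicate 2 (0.0532). Spindle (0.0573), cohesion (0.0971) and prophase arrest genes (0.701) did not pass at FGO. When members could change either way, 27 of 28 lists passed fry at FGO, these 3 included.

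At nFGO the fry call of MPF genes (adjusted p = 0.00408) held with quantile normalization (0.00763) and with every library left out (up to 0.0388). Their median was -0.19, and -0.11 with quantile normalization. Maternal-effect (0.0103) and spindle genes (0.0124) passed fry at nFGO, also with quantile normalization (0.0362 and 0.0123). With 1 library left out both were lost, up to 0.0541 and 0.122. Cohesion (0.0182) and anaphase-promoting complex/spindle checkpoint genes (0.0217) lost the call with quantile normalization (0.0883 and 0.292). At GO2, anaphase-promoting complex/spindle checkpoint and maternal-effect genes (both 0.0449) lost it too (0.641 and 0.709). The anaphase-promoting complex/spindle checkpoint call at GO1 (0.0135) was lost with equal library medians (0.0815).

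Heat shock genes were lower by fry at GO1 (adjusted p = 0.00191), GO2 (0.00322), nFGO (0.000123) and FGO (0.0216). The FGO call was lost with quantile normalization (0.166) and equal library medians (0.0619). Cholesterol synthesis genes were lower by fry at GO1 (0.00191), GO2 (0.0449), nFGO (0.00253) and FGO (0.00722), and with quantile normalization (0.000683, 0.0338, 0.00103 and 0.00254). Their GO2 call was lost with the 5 RPKM filter (0.125), pseudocounts of 0.1 (0.0513) and 5 (0.0503) and without any 1 of 12 libraries. Their FGO call was lost without KO FGO replicate 2 (0.0532).

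Of genes of the unfolded protein and integrated stress response at FGO, 7 of 21 rose and 2 fell over all genes (10 and 3 adjusted over the list alone), camera adjusted p = 0.0105, and adjusted p = 0.154 with an estimated correlation, and 0.185 with the 5 RPKM filter. The preset-correlation call held with every library left out, and fry gave adjusted p = 0.000193. Herpud1, which encodes a protein of endoplasmic reticulum degradation, rose from 0.177 ± 0.138 to 3.97 ± 0.46 RPKM (log2 fold change 2.08, adjusted p = 0.00054). Psat1, of serine synthesis, rose from 0.212 ± 0.3 to 3.15 ± 1.44 RPKM (log2 fold change 1.75, adjusted p = 0.00242). Chac1, of glutathione breakdown, rose from 1.38 ± 0.263 to 4.75 ± 0.809 RPKM (log2 fold change 1.27, adjusted p = 0.000662), and Eif4ebp1, a repressor of cap-dependent translation from the growth kinase list, from 2.95 ± 0.284 to 15.8 ± 2.76 RPKM (log2 fold change 2.08, adjusted p = 0.000306). Asns rose from 3.48 ± 0.205 to 13.6 ± 4.44 RPKM (log2 fold change 1.67, adjusted p = 0.0105), but lost its call without WT FGO replicate 2 and without KO FGO replicate 2.

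**Figure D3:**
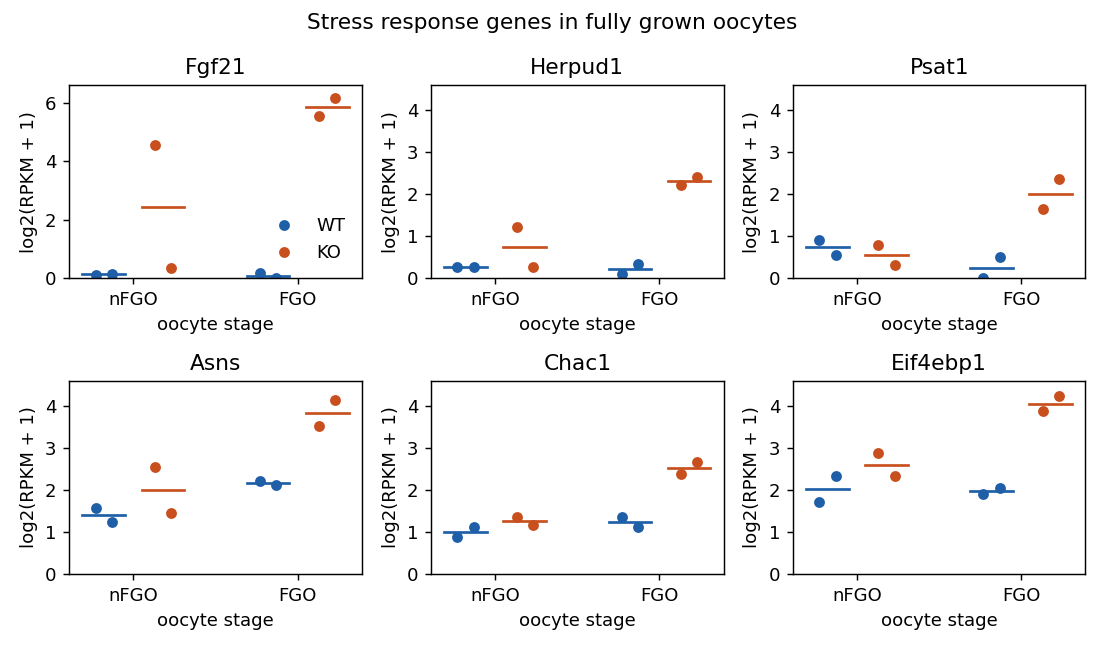
Levels of 6 genes, as log2(RPKM + 1), in each fully grown library (points, n = 2 per group) with the group mean (bar). Fgf21 was at 45.5 and 70.7 RPKM in KO FGO and at 22.6 and 0.27 RPKM in KO nFGO.

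Genes of metabolism and protein synthesis changed singly at FGO. The complex I gene Ndufb7 fell from 143 ± 26.6 to 41.6 ± 8.09 RPKM (log2 fold change -1.76, adjusted p = 4.95e-05) and Ndufa4l2 rose (1.72, adjusted p = 0.00316). Aldoc (1.79, adjusted p = 0.00283), Slc2a1 (0.70, adjusted p = 0.00442), Hist1h4d (1.87, adjusted p = 0.00134), Psmb11 (1.20, adjusted p = 0.00129), Rpl3 (0.82, adjusted p = 0.00363), Rpl9 (0.71, adjusted p = 0.00313) and Rps3 (0.69, adjusted p = 0.00667) rose. Rpl5 (-0.70, adjusted p = 0.000508), Psmd14 (-0.70, adjusted p = 0.00221), Hspb1 (-1.73, adjusted p = 0.00509) and Rps6ka3 (-0.91, adjusted p = 0.000238) fell. Of oxidative phosphorylation genes, 6 of 86 rose and 14 fell over all genes (6 and 17 adjusted over the list alone), camera adjusted p = 0.164, with 0.0153 without WT FGO replicate 1 and 0.0302 without KO FGO replicate 1. Of ribosomal protein genes, 5 of 85 rose and 4 fell over all genes (4 and 3 adjusted over the list alone), camera adjusted p = 0.679, and 0.041 with quantile normalization. Of zona genes, 1 of 22 rose and 2 fell over all genes (0 and 2 adjusted over the list alone), camera adjusted p = 0.373, and 0.0199 without WT FGO replicate 1.

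In limma at FGO, 2596 genes passed the test, 1116 higher and 1480 lower, 757 of them changed at least 2-fold. Quantile normalization gave 1310 higher and 1331 lower, and the 4 libraries of the stage alone 1072 genes. The count was 1619 without WT FGO replicate 1, 1590 without WT FGO replicate 2, 1632 without KO FGO replicate 1 and 1193 without KO FGO replicate 2.

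**Figure D4:**
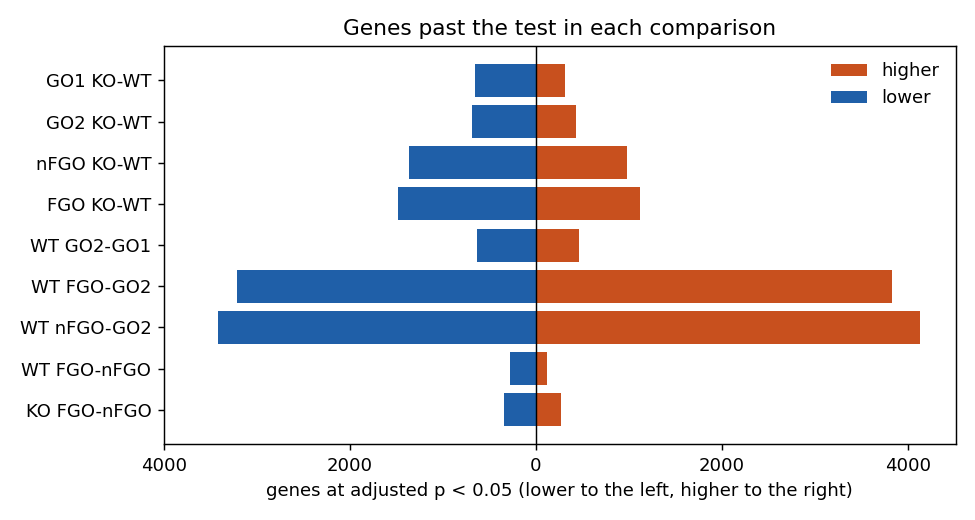
Genes at adjusted p under 0.05 in each comparison (limma, n = 2 libraries per group), lower to the left and higher to the right. KO against WT gave 965 genes at GO1 and 2596 at FGO.

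Across stages, 21 genes, Mt1 and Tfec among them, were higher in KO at all 4, and 85, Smarca5 and Akr1b8 among them, were lower at all 4. The nFGO and FGO effects, from separate libraries, shared 528 genes higher at both (75.5 expected if independent) and 814 lower at both (139 expected), with 5 genes in opposite directions. Their log2 fold changes had r = 0.662 across genes, which are not independent replicates. For GO1 and GO2, 38 were higher at both (9.3 expected), 140 lower at both (30.5 expected) and 42 opposite, with r = 0.222 across genes. In all 4587 genes were called at 1 stage or more, and 106 of them in opposite directions at different stages.

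As WT oocytes grew from GO2 to FGO, Lmo3, which encodes a LIM-only transcription cofactor, rose from 0.454 ± 0.149 to 68.6 ± 7.15 RPKM (log2 fold change 5.58, adjusted p = 2.93e-08). The long noncoding RNA Malat1 fell from 1044 ± 41.3 to 28.1 ± 6.21 RPKM (log2 fold change -5.18, adjusted p = 1.13e-07), and the inhibitor of differentiation gene Id3 from 164 ± 26.2 to 4.53 ± 2.48 RPKM (log2 fold change -4.97, adjusted p = 1.13e-07). Lcp2 (5.27, adjusted p = 7.5e-07), Selp (4.89, adjusted p = 2.93e-08) and Robo2 (4.41, adjusted p = 1.27e-07) rose. Tcp11l1 (-4.68, adjusted p = 6.32e-08), Selenos (-4.50, adjusted p = 7.03e-08) and Zfp707 (-4.46, adjusted p = 7.32e-07) fell. The meiotic genes Mei4 (3.91, adjusted p = 6.84e-07), Ccnb3 (1.80, adjusted p = 9e-06), Bub1b (1.59, adjusted p = 5.28e-06), Fbxo43 (1.21, adjusted p = 0.00222) and Aurka (0.96, adjusted p = 3.01e-05) rose. Wee1 (-2.04, adjusted p = 9.62e-06), Sycp3 (-2.80, adjusted p = 8.93e-06), Ddx4 (-2.65, adjusted p = 5.12e-07), Xbp1 (-2.77, adjusted p = 3.89e-06) and Zp1 (-1.26, adjusted p = 1.4e-06) fell. All are mean ± SD of n = 2 libraries.

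MPF genes were higher at FGO than at GO2 in WT: 11 of 22 rose and 2 fell over all genes (13 and 3 adjusted over the list alone), camera adjusted p = 0.0466, and adjusted p = 0.655 with an estimated correlation. The call was lost without WT FGO replicate 1 (0.0927), with quantile normalization (0.0849) and with the 5 RPKM filter (0.0818). Oxidative phosphorylation genes, with Uqcrc1 (-3.61, adjusted p = 5.6e-06), were lower: 4 of 86 rose and 41 fell over all genes (4 and 41 adjusted over the list alone), camera adjusted p = 2.15e-05, and adjusted p = 0.655 with an estimated correlation. Ribosomal protein genes, with Rps23 (-2.54, adjusted p = 2.18e-07), were lower: 5 of 85 rose and 28 fell over all genes (4 and 27 adjusted over the list alone), camera adjusted p = 0.00577, and adjusted p = 0.764 with an estimated correlation. By limma 7048 genes passed, 3831 higher and 3217 lower (2785 changed at least 2-fold). Quantile normalization gave 3474 higher and 3525 lower. With each library left out the count stayed between 5277 and 5880.

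From GO2 to nFGO, Lmo3 (5.18, adjusted p = 1.86e-08), Lcp2 (6.09, adjusted p = 2.52e-07), Selp (4.83, adjusted p = 1.86e-08), Csmd3 (4.49, adjusted p = 2.48e-08), Mei4 (3.81, adjusted p = 6.82e-07), Bub1b (2.18, adjusted p = 4.35e-07) and Cdc25a (1.20, adjusted p = 1.61e-05) rose. Malat1 (-4.29, adjusted p = 2.94e-07), Id3 (-4.55, adjusted p = 1.7e-07), Tcp11l1 (-4.64, adjusted p = 4.82e-08), Wee1 (-2.34, adjusted p = 3.05e-06), Sycp3 (-2.74, adjusted p = 9.15e-06) and Ddx4 (-2.76, adjusted p = 3.21e-07) fell. MPF genes were higher: 15 of 22 rose and 2 fell over all genes (15 and 2 adjusted over the list alone), camera adjusted p = 0.0294, and adjusted p = 0.678 with an estimated correlation, lost with quantile normalization (0.107) and the 5 RPKM filter (0.0771). Oxidative phosphorylation genes were lower: 7 of 86 rose and 33 fell over all genes (7 and 33 adjusted over the list alone), camera adjusted p = 0.0127, and adjusted p = 0.877 with an estimated correlation. By limma 7551 genes passed, 4137 higher and 3414 lower (3196 changed at least 2-fold), and 5832 to 6278 with each library left out. Quantile normalization gave 3697 higher and 3878 lower. The nFGO libraries differ from GO2 in their molecule label too, so stage and a possible batch are not separated here.

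Between the growing stages of WT, Defb41 rose from 21.9 ± 0.486 to 133 ± 2.49 RPKM (log2 fold change 2.55, adjusted p = 0.00345). The deubiquitinase gene Usp3 fell from 329 ± 5.56 to 98.9 ± 9.31 RPKM (log2 fold change -1.73, adjusted p = 0.000165) and the sodium channel gene Scn10a from 12.1 ± 2.86 to 2.92 ± 0.0169 RPKM (log2 fold change -1.73, adjusted p = 0.00345). These and Cyp2c53-ps (-1.73, adjusted p = 0.000423) were the 4 of 75 listed genes that kept their call with every library left out. Of glycolysis genes, 0 of 14 rose and 3 fell over all genes (0 and 4 adjusted over the list alone), camera adjusted p = 0.000546, and adjusted p = 0.0965 with an estimated correlation. Pkm (-1.31, adjusted p = 0.00757) fell and lost its call without WT GO1 replicate 2 or WT GO2 replicate 1. Of ribosomal protein genes, 14 of 85 rose and 0 fell over all genes (30 and 1 adjusted over the list alone), camera adjusted p = 1.09e-09, and adjusted p = 0.373 with an estimated correlation. Of oxidative phosphorylation genes, 13 of 86 rose and 3 fell over all genes (19 and 4 adjusted over the list alone), camera adjusted p = 0.000527, and adjusted p = 0.552 with an estimated correlation, lost with quantile normalization (0.0537). Of proteasome genes, 0 of 36 rose and 7 fell over all genes (1 and 11 adjusted over the list alone), camera adjusted p = 0.00614, and adjusted p = 0.552 with an estimated correlation. Of DNA and histone methylation genes, 3 of 32 rose and 1 fell over all genes (3 and 2 adjusted over the list alone), camera adjusted p = 0.0495, and adjusted p = 0.552 with an estimated correlation, lost without WT GO1 replicate 1 (0.131) or WT GO2 replicate 2 (0.12). That call was also lost with quantile normalization (0.0537), equal library medians (0.0509) and a pseudocount of 0.1 (0.055). In limma 1099 genes passed, 462 higher and 637 lower (191 changed at least 2-fold). The count was 108 without WT GO1 replicate 1, 24 without WT GO1 replicate 2, 13 without WT GO2 replicate 1 and 291 without WT GO2 replicate 2.

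Genes lower in KO at FGO, such as Mei4, Ccnb3 and Ago2, were often genes that rise as WT oocytes grow. Of the 1480 genes lower in KO at FGO, 49.4 percent rose and 14.7 percent fell from WT GO2 to WT nFGO, 2 groups that share no library with that comparison. Of the 1116 genes higher in KO, 18 percent rose and 41 percent fell (Fisher's exact test, odds ratio 7.66, p = 3.82e-79, across genes, which are not independent replicates). Among uncalled genes 26.8 percent rose and 22.9 percent fell. The sets were not matched for WT level. A gene must be expressed in WT FGO oocytes to be called lower in KO there. WT FGO and WT nFGO libraries were alike, at r = 0.975 to 0.98 across genes. This choice by level can favour genes that rise, so the tests in this part cannot show a link of the KO effect to growth. For nFGO, set against WT FGO and GO2, 45.6 percent of genes lower in KO rose and 24.5 percent of genes higher in KO (Fisher's exact test, odds ratio 4.23, p = 1e-35). At GO2, set against WT nFGO and GO1, the shares were 35.2 percent of genes lower in KO and 53.1 percent of genes higher in KO (Fisher's exact test, odds ratio 0.338, p = 3.93e-11).

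With hormone against without, in WT, Mia3 rose from 2.01 ± 0.251 to 56.4 ± 14.6 RPKM (log2 fold change 4.23, adjusted p = 6.12e-08) and the palmitoyltransferase gene Zdhhc2 fell from 72 ± 4.11 to 0.671 ± 0.4 RPKM (log2 fold change -5.47, adjusted p = 5.03e-07). The pseudogenes Rps27a-ps2 (4.21, adjusted p = 5.03e-07), Vamp7-ps (3.92, adjusted p = 7.85e-08) and Tes3-ps (2.68, adjusted p = 8.4e-06) rose, and Rpl7a (-2.13, adjusted p = 3.14e-05), Foxj3 (-1.77, adjusted p = 0.000198) and Ppia (-1.68, adjusted p = 1.28e-05) fell. In KO oocytes the same comparison gave Mia3 (4.77, adjusted p = 7.52e-08), Rps27a-ps2 (3.54, adjusted p = 3.37e-06), Vamp7-ps (3.52, adjusted p = 4.2e-07), Tes3-ps (2.58, adjusted p = 1.38e-05), Zdhhc2 (-5.56, adjusted p = 5.25e-07) and Rpl7a (-2.21, adjusted p = 2.5e-05). Ribosomal protein genes were lower in WT: 0 of 85 rose and 9 fell over all genes (0 and 13 adjusted over the list alone), camera adjusted p = 1.43e-09, and adjusted p = 0.677 with an estimated correlation. Of oxidative phosphorylation genes in WT, 1 of 86 rose and 2 fell over all genes (2 and 10 adjusted over the list alone), camera adjusted p = 0.00345, and adjusted p = 0.814 with an estimated correlation, lost without WT nFGO replicate 1 (0.0872) or WT FGO replicate 1 (0.342). Hormone treatment and a possible batch fall together in this comparison and cannot be separated. By limma 392 genes passed in WT, 118 higher and 274 lower (168 changed at least 2-fold; n = 2 libraries per group). The count was 204 without WT nFGO replicate 1, 127 without WT nFGO replicate 2, 270 without WT FGO replicate 1 and 203 without WT FGO replicate 2.

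In KO oocytes too, hormone treatment and a possible batch fall together and cannot be separated. Stress genes were higher at FGO than at nFGO in KO: 6 of 21 rose and 0 fell over all genes (7 and 2 adjusted over the list alone), camera adjusted p = 0.00483, and adjusted p = 0.195 with an estimated correlation, lost with the 5 RPKM filter (0.156). Chac1 (1.25, adjusted p = 0.0026) rose with every library left out, and Asns (1.83, adjusted p = 0.022), Herpud1 (1.56, adjusted p = 0.0105) and Psat1 (1.45, adjusted p = 0.0227) rose and each lost its call without KO nFGO replicate 2 or KO FGO replicate 2. Ribosomal protein genes were lower: 0 of 85 rose and 17 fell over all genes (1 and 34 adjusted over the list alone), camera adjusted p = 2.39e-12, and adjusted p = 0.339 with an estimated correlation. Oxidative phosphorylation genes were lower: 0 of 86 rose and 12 fell over all genes (2 and 30 adjusted over the list alone), camera adjusted p = 4.47e-07, and adjusted p = 0.339 with an estimated correlation. Histone genes were lower: 0 of 27 rose and 1 fell over all genes (0 and 4 adjusted over the list alone), camera adjusted p = 0.00483, and adjusted p = 0.339 with an estimated correlation. By limma 616 genes passed, 271 higher and 345 lower (173 changed at least 2-fold), and quantile normalization gave 368 and 264. The count was 266 without KO nFGO replicate 1, 142 without KO nFGO replicate 2, 369 without KO FGO replicate 1 and 152 without KO FGO replicate 2. The WT and KO differences, from separate libraries, shared 64 genes higher in both (2.2 expected) and 97 lower in both (6.49 expected), with r = 0.452 across genes, which are not independent replicates. The nFGO libraries of both genotypes carry the polyA RNA label, so a shared batch would also give this agreement.

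A batch drops out of the genotype by hormone interaction only if it shifts both genotypes equally on this log2 scale, which was not tested. There, Mthfsd (2.16, adjusted p = 0.018) had a more positive KO effect at FGO, a call lost without KO nFGO replicate 2 or KO FGO replicate 1. Chchd10 (-1.03, adjusted p = 0.018) had a more negative one, a call lost without WT nFGO replicate 2, KO nFGO replicate 2, WT FGO replicate 1 or KO FGO replicate 1. Stress response genes had a more positive effect at FGO, by a median of 0.33: 0 of 21 genes passed with a more positive and 0 with a more negative effect over all genes (4 and 0 adjusted over the list alone), camera adjusted p = 0.000239, and adjusted p = 0.0425 with an estimated correlation. With each library left out this adjusted p ran from 5.84e-05 to 0.00608 at the preset correlation. With the estimated correlation the call stayed only without KO nFGO replicate 1 (0.0351) or either KO GO1 replicate (0.0465), and was lost without any 1 of the other 13 libraries, up to 0.165 without KO FGO replicate 2. It was also lost with the 5 RPKM filter (0.186) and a pseudocount of 0.1 (0.0664). Of heat shock genes, 0 of 12 genes passed with a more positive and 0 with a more negative effect over all genes (1 and 0 adjusted over the list alone), camera adjusted p = 0.0184, and adjusted p = 0.107 with an estimated correlation, lost without KO nFGO replicate 1 (0.0671), WT FGO replicate 1 (0.0792) or KO FGO replicate 2 (0.0562), and with the 5 RPKM filter (0.0584). Of other chromatin remodellers, 0 of 32 genes passed with a more positive and 0 with a more negative effect over all genes (2 and 0 adjusted over the list alone), camera adjusted p = 0.0137, and adjusted p = 0.0762 with an estimated correlation, lost without WT FGO replicate 2 (0.12) or KO FGO replicate 2 (0.0562). Of oxidative phosphorylation genes, 0 of 86 genes passed with a more positive and 0 with a more negative effect over all genes (0 and 0 adjusted over the list alone), camera adjusted p = 0.0366, and adjusted p = 0.915 with an estimated correlation, lost without WT nFGO replicate 2 (0.27), KO nFGO replicate 1 (0.146), WT FGO replicate 2 (0.779) or KO FGO replicate 2 (0.594), and with quantile normalization (0.868). By limma 9 genes passed, 3 more positive and 6 more negative, with 1205 at an unadjusted p under 0.05, and quantile normalization gave 3 and 3. With no variance trend 4 genes passed. The count was 17 without WT nFGO replicate 1, 7 without WT nFGO replicate 2, 18 without KO nFGO replicate 1 and 2 without KO nFGO replicate 2. It was 7 without WT FGO replicate 1, 28 without WT FGO replicate 2, 6 without KO FGO replicate 1 and 11 without KO FGO replicate 2.

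The KO effect at nFGO was more positive than at GO2 for Hist1h1e (2.45, adjusted p = 0.00494) and Klhdc8b (2.41, adjusted p = 0.013). It was more negative for Akr1b8 (-2.96, adjusted p = 0.00409), Reg3g (-3.09, adjusted p = 0.0024), Nrcam (-2.52, adjusted p = 0.00747) and Atrx (-1.29, adjusted p = 0.00409). Ribosomal protein genes had a more positive effect at nFGO: 8 of 85 genes passed with a more positive and 0 with a more negative effect over all genes (37 and 0 adjusted over the list alone), camera adjusted p = 1.57e-18, and adjusted p = 0.346 with an estimated correlation. Of oxidative phosphorylation genes, 6 of 86 genes passed with a more positive and 0 with a more negative effect over all genes (11 and 0 adjusted over the list alone), camera adjusted p = 9.51e-09, and adjusted p = 0.346 with an estimated correlation. By limma 462 genes passed, 212 more positive and 250 more negative. Equal library medians gave 282 and 234. The count was 146 without WT GO2 replicate 1, 107 without WT GO2 replicate 2, 168 without KO GO2 replicate 1 and 31 without KO GO2 replicate 2. It was 215 without WT nFGO replicate 1, 120 without WT nFGO replicate 2, 73 without KO nFGO replicate 1 and 301 without KO nFGO replicate 2.

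In the DESeq output of the authors, Smarca5, Mt1 and Akr1b8 have the direction given above at every stage. The authors' groups hold 590 genes up and 691 down at GO1, 718 and 740 at GO2, 845 and 999 at nFGO, and 1096 and 1183 at FGO. Of the genes called here by limma, 99.1, 99.2, 98.9 and 99.4 percent shared the direction of the authors' fold change at GO1, GO2, nFGO and FGO. The 2 sets of calls, made from the same libraries, shared 541, 663, 1345 and 1627 genes. The authors' called genes all had a log2 fold change of at least 0.585 in size and a DESeq p under 0.05. The calls here used an adjusted p and no fold threshold, so the 2 sets are not on like terms.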

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

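The tests of a metal response, of the chromatin around Mt1, of the Cre transgene, of the RPKM estimate and of the point of growth were chosen only after the results were seen, while the tests of knockout oocytes in a wild-type library and of swapped stage labels were written before. The KO effect differed between stages for 9 genes (FGO against nFGO), 582 genes (GO2 against GO1) and 462 genes (nFGO against GO2). It also differed for ribosomal protein genes (1.83e-35) and oxidative phosphorylation genes (3.78e-24) between GO2 and GO1, and for stress response genes (0.000239) between FGO and nFGO, as camera adjusted p of limma at the preset correlation. With an estimated correlation these were 0.0492, 0.0492 and 0.0425, and each was lost without any 1 of 13 of the 16 libraries.

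Mt1 was 1310 RPKM or more in all 8 KO libraries and 7.7 RPKM or less in all WT libraries. A metal response through MTF1 may raise Mt1 and its other targets; the highest log2 fold change of Slc30a1 was 0.41 (adjusted p = 0.398), at a mean of 4.34 RPKM that is too low to decide. Opening of the chromatin around the Mt gene cluster was tested only through the RNA of the neighbours Bbs2, Mt4 and Nup93. Of these, 0 of 3 were called higher at 2 or more stages. Neighbour RNA is not a measure of chromatin and the ATAC-seq samples were not analysed, so this test cannot exclude an opening. Mt2, the metallothionein gene next to Mt1, is not in the deposited table, so a narrower opening at Mt1 and Mt2 stays open, and Mt2 could not serve in the other tests. Mt1 sequence carried by the Cre transgene could give a full effect from GO1 on: the GO1 effect was 98 percent of that at nFGO, against a median of 88.7 percent in 105 other genes, 42 of which were at or above Mt1, so this test did not decide. A direct effect of Snf2h loss on Mt1 stays open and was not tested.

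Smarca5 was 13.9 RPKM in WT FGO replicate 2 and 48.7 RPKM in replicate 1. Knockout oocytes in that library could lower it, at a share of 72.6 percent, but over 2352 genes the library lay 4.4 percent of the way from WT replicate 1 to the KO mean. Its Mt1 level was 7.7 RPKM, where that share would give 1500 RPKM. The RPKM estimate of that library rather than its reads was tested with the authors' count mean for Smarca5, which stood at percentile 48.7 of 6790 genes, so the counts are low as well. The cause of the low value remains open.

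Ribosomal protein and oxidative phosphorylation genes moved in opposite directions in KO at GO1 and GO2, in both replicates of each group. Swapped stage labels in 1 genotype would turn the GO2 less GO1 changes of WT and KO against each other, but their r was 0.274 across genes, which are not independent replicates. Oocytes of the genotypes at different points of growth within a size class could also do this; along an axis from growing WT to WT nFGO libraries KO GO1 was shifted by -0.355 percent, within the range of the replicates, and KO GO2 by 9.38 percent. That axis is defined from WT libraries of the same stages. On axes that share no library with the stage, both KO libraries lay below both WT libraries at GO1 (shifts of -5.01 percent toward nFGO and -7.2 percent toward FGO). These shifts came mostly from KO GO1 replicate 1, without which they were -1.09 and -2.06 percent, and 1.81 percent on the first axis. Both lay above them at GO2 (5.79 and 7.51 percent, or 2.63 and 3.86 percent without WT GO2 replicate 2). The axes disagree at GO1 and the GO1 shift rests on 1 library, so a difference in the point of growth stays open. A direct effect of genotype on these 2 gene groups also stays open. The KO-WT list tests above cannot tell it from a difference in the point of growth.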

How the results depend on the processing

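The alternatives that keep calls sharing the authors' direction and that leave out small RNA and pseudogene symbols were chosen only after the results were seen. Of 10659 values of named genes other than Smarca5, 0 reversed. These genes were named because they were called in the same data, so this 0 does not measure stability. With 1 library left out, the counts of genes ran from 231 to 2741 at GO1, 61 to 452 at GO2, 960 to 1374 at nFGO, 1193 to 1632 at FGO, 13 to 291 for WT GO2 against GO1, 127 to 270 for FGO against nFGO in WT and 142 to 369 in KO. The interactions ran from 2 to 28 (FGO and nFGO), 4 to 2402 (GO2 and GO1) and 31 to 301 (nFGO and GO2). In the 4 KO-WT comparisons 13 list tests were called with all libraries, 8 under the 5 RPKM filter, 8 with no variance trend and 0 with an estimated correlation. This number also moved with 1 library left out. Smarca5 stayed called, from -4.03 to -3.80 at GO1, -4.29 to -3.67 at GO2, -4.45 to -4.36 at nFGO and -4.77 to -3.04 at FGO. With only the 4 libraries of a stage the counts were 16 at GO1, 291 at GO2, 1174 at nFGO and 1072 at FGO. With no variance trend the interactions gave 4 (FGO and nFGO) and 101 (GO2 and GO1). For single named genes 2317 of 10659 values (21.7 percent) were no longer called, 1592 of 3696 (43.1 percent) with 1 library left out. The cause was not tested for any of these changes.

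A replicate block, by replicate number within each stage, gave 596 genes at GO1 and 555 at GO2, and 0 (FGO and nFGO), 5 (GO2 and GO1) and 136 (nFGO and GO2) in the interactions. The labels do not say that replicate 1 of WT and of KO belong together. The deviations of WT and KO replicate 1 correlated across genes at -0.008 at GO1, -0.019 at GO2, 0.073 at nFGO and 0.096 at FGO. These low values neither show nor exclude a pairing, and the block is not used elsewhere.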

Other observations

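The growth-axis positions, pseudogene counts and list tests outside the KO-WT comparisons given here were chosen only after the results were seen. Fgf21 was 45.5 and 70.7 RPKM in the KO FGO libraries, 0.13 and 0 RPKM in WT FGO, and 22.6 and 0.27 RPKM in KO nFGO, with the 2 KO nFGO replicates apart. Along the axis set by construction from the mean of the WT GO1 and GO2 libraries (0 percent) to that of WT nFGO (100 percent), KO nFGO lay at 83.1 and 85.3 percent, KO FGO at 73.0 and 69.2 percent and WT FGO at 84.8 and 83.4 percent. Snora47 had a KO log2 fold change of -5.05 at GO1 and 3.72 at GO2. Small RNA symbols were kept out of the listed genes, so its values with libraries left out were not scored. The spread between replicates was largest in KO GO1, at an SD of 0.476 for the log2 difference.

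Of oocyte transcription factors at FGO, 1 of 14 rose and 0 fell over all genes (1 and 0 adjusted over the list alone), camera adjusted p = 0.859. Of translational control genes, 1 of 35 rose and 5 fell over all genes (1 and 5 adjusted over the list alone), camera adjusted p = 0.634. Of ISWI complex genes, 2 of 12 rose and 2 fell over all genes (2 and 2 adjusted over the list alone), camera adjusted p = 0.731, with the deleted gene Smarca5 as 1 of those that fell. Of other chromatin remodellers, 0 of 32 rose and 2 fell over all genes (0 and 2 adjusted over the list alone), camera adjusted p = 0.731. Of piRNA and transposon genes, 2 of 21 rose and 5 fell over all genes (4 and 8 adjusted over the list alone), camera adjusted p = 0.679. Of 2-cell stage genes at FGO, 2 of 11 rose and 3 fell over all genes (2 and 3 adjusted over the list alone), camera adjusted p = 0.859. Of imprinted genes, 3 of 20 rose and 2 fell over all genes (4 and 2 adjusted over the list alone), camera adjusted p = 0.679. Of p53 and DNA damage genes, 1 of 19 rose and 3 fell over all genes (1 and 4 adjusted over the list alone), camera adjusted p = 0.756. Of growth kinase genes, 3 of 29 rose and 2 fell over all genes (3 and 3 adjusted over the list alone), camera adjusted p = 0.705. Of cholesterol synthesis genes at FGO, 0 of 19 rose and 4 fell over all genes (0 and 4 adjusted over the list alone), camera adjusted p = 0.36. Of glycolysis genes at FGO, 2 of 14 rose and 1 fell over all genes (2 and 1 adjusted over the list alone), camera adjusted p = 0.679. Of calcium and egg activation genes, 0 of 17 rose and 0 fell over all genes (0 and 0 adjusted over the list alone), camera adjusted p = 0.731. Of proteasome genes, 5 of 36 rose and 4 fell over all genes (5 and 5 adjusted over the list alone), camera adjusted p = 0.36. Of theca and stroma markers, 1 of 5 rose and 1 fell over all genes (1 and 1 adjusted over the list alone), camera adjusted p = 0.859. Of the 3 tested blood and endothelial markers, 0 of 3 rose and 0 fell over all genes (0 and 0 adjusted over the list alone), with too few for camera. No cumulus marker and no mitochondrially encoded transcript was tested, since 0 of 3 cumulus markers passed the filter and 0 mitochondrially encoded symbols were in the table.

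Of proteasome genes at GO1, 0 of 36 rose and 2 fell over all genes (0 and 2 adjusted over the list alone), camera adjusted p = 0.35, and 0.0417 without KO GO1 replicate 2. Theca and stroma markers had 0.0192 at GO2 without WT GO2 replicate 2. Symbols ending in -ps made up 2.3 percent of the WT and 2.11 percent of the KO calls of FGO against nFGO, against 1.36 percent of the tested genes (Fisher's exact test, p = 0.116 and 0.107). Their share was lower in WT growth, at 1.01 percent for nFGO against GO2, 0.922 percent for FGO against GO2 and 0.637 percent for GO2 against GO1. Fisher's exact test gave p = 0.000138, 1.08e-05 and 0.0293 there. In the KO-WT comparisons the share ran from 0.963 to 1.17 percent.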
